A study of Rattus norvegicus with 8 samples.

How the data were processed

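NR8383 rat alveolar macrophages were grown in wells, exposed for 24 h and lysed for total RNA, per the labels' protocols. The exposure was exfoliated graphene at 0.01 mg/mL in a working solution with bovine serum albumin, and the control was that named for this exposure. Cy3-labelled cRNA was hybridised to 1-colour Agilent arrays, 1 array for each of 4 samples per group, and images were read with Agilent Feature Extraction 12.0.3.1, per the submitters' processing notes. Samples were assigned to groups from their titles alone.

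The table used holds 41103 probes by 8 arrays of deposited values on a logarithmic scale. The base of the logarithm is not given in the sources used here. Values of a probe spanned up to 10.5 units, too wide for base 10, and base 2 was taken, while a natural logarithm was not excluded and would make every fold larger. The median of the 4 control arrays was 0 for every probe (to within 5e-07), so the authors had subtracted it from each deposited log2 value. The direction is then signal relative to the controls. Whether the arrays had been scaled to each other before is not given. The median of the tested probes lay between -0.05 and 0.07 on the 8 arrays, and no further scaling was applied. Absolute signals and detection flags were not part of the values used, so the depth above background of a probe is known only as described next. A further table served as probe annotation only, and its 2 columns of values, which name no sample or group, were not used.

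Probe names were matched to gene identifiers in that annotation. Of 41012 probes other than the 91 control probes, 25337 carried a gene identifier and 15675 did not. Of 18528 gene identifiers, 17690 were found in a table of current rat gene names (assembly GRCr8, used for names only), which changed the symbol of 3025, and the others kept the symbol of the annotation.

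The planned filter on detection flags could not be applied to centred values. Instead, a filter and its limits were chosen after the values were seen. The 12 control probes named RC share 1 profile over the 8 arrays, taken here as the background level of each array. A probe at the background follows this profile. Probes with at least 3 arrays within 0.06 of their own lowest value after subtraction of the profile, with at least 1 such array in each group, were left out. This removed 4214 probes and kept 36798. Profiles shuffled over the arrays removed 396 on average in 20 draws. A gene whose probes followed the profile on all 4 arrays of a group has only a bound there, and its fold is given as at least that of the other group's mean over this background. Without the filter, 373 of the 4214 removed probes would have been called, all of them lower, with a median log2 change of -0.36 over the removed probes, near the difference of -0.43 in background level.

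Values of the remaining probes of a gene were averaged, since centred values do not show which probe is brightest, as had been planned. Probes with no gene were kept as features of their own and counted apart. The 30785 features, 17029 of them genes with a symbol, were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term and equal weights. P-values are two-sided and were adjusted by Benjamini-Hochberg over all features, and a feature was called at an adjusted p under 0.05. Of 4574 genes with several probes, 65 had probes called in opposite directions.

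The 32 gene lists, the rule for named genes and the test of lists were fixed before the data were examined, while the filter, the averaging of probes and the use of the values without an upper-quartile shift replaced steps that need signals. The lists hold 675 genes, of which 654 were found on the array, and the last 4 lists hold markers of cells other than macrophages. Lists with at least 4 measured genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, and fry in its directional and mixed forms, were the alternatives. Lists were at first to count as leading results only if they passed camera with both correlations. None did, and after that the 8 that passed with the preset correlation were taken. Named genes were, among called genes whose groups did not overlap, the 12 with the largest rise and the 12 with the largest fall, passing over uncharacterised names. In addition up to 3 called members in each direction were taken from each list, or the 2 with the smallest p where none was called. Other members named are examples from the lists, chosen after their values were seen. They are Relb, Nfkbia, Tnf, Mki67, Top2a, Bub1, Cdkn1a and Slc16a3.

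The alternatives run were a median shift of each array, no filter, a stricter filter, the replicate number as a block, array quality weights, other thresholds and leaving out each array in turn. Added after the data were seen were robust empirical Bayes, each probe as its own feature, the fit without control replicates 1 and 2, and the level of the 10 E1A spike-in probes as a covariate. With each probe as its own feature, probes of the same gene enter camera as separate members. They are not independent, so list p-values from that setting may be too small. Checks that need raw signals or slide numbers had been intended and were not run. These are quantile normalisation, normexp background correction, a mean-variance trend and a slide block. The value table planned as an alternative source was itself the source.

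The filter and the fit were tested on simulated data with the 30785 features of this comparison, 200 of them changed. Of 50 genes changed by each size, 16% were recovered at a log2 change of 0.5, 58% at 1, 78% at 2 and 54% at -1, and 6 of 109 calls were false. The simulation was first required to recover 45 of 50 genes at a log2 change of 2. It recovered 39, and after that result the requirement was replaced by a looser one, an average estimate within 0.2 of 2 and more recovered than at 0.5. The data gave far more calls, 5803 of 17029 genes, which makes the adjustment less strict than in the simulation. The simulated recovery rates therefore do not describe this comparison. Real changes, large ones included, can still be missed, at a rate that is not known. The filter removed 100% of simulated background probes and 0.5% of simulated flat probes. How many real dim probes escaped the filter is not shown by these rates. Single values of arrays were compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.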

Results

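Gene expression was measured in NR8383 cells, an established line of rat alveolar macrophages, the phagocytes that clear inhaled particles from the air spaces of the lung. The cells were cultured for 24 h with exfoliated graphene (EGr), thin sheets of carbon split from graphite, at 0.01 mg/mL, or as a control made for that exposure. Each group held 4 arrays, 8 in all, and each array was hybridised with Cy3-labelled cRNA. The comparison asks which genes of the macrophages differed after exposure to graphene. Values are log2 signals relative to the median of the 4 control arrays for each probe, and every fold change below takes base 2, which the sources used here do not state. The number of arrays limits the precision. The labels call the arrays of a group replicates without saying whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical. Changes are given as log2 fold change, EGr minus control, ± SE from limma, with n = 4 arrays per group throughout.

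After 24 h with graphene, genes of cell division were lower and genes of NF-kB signalling and of several cytokines were higher than in the controls. As lists, the mitotic, DNA replication, NF-kB and cytokine genes passed camera with a preset correlation but not with an estimated correlation (adjusted p = 0.084, 0.084, 0.084 and 0.288), and 7 of 24 NF-kB targets were not called and 3 of 21 cytokine genes fell. The mitotic kinase Plk1 fell by 2.05 ± 0.09 and the cyclin Ccnb2 by 1.91 ± 0.12, while inducible nitric oxide synthase Nos2 rose by 1.90 ± 0.09 and the activin subunit gene Inhba by 3.13 ± 0.09. Of 17029 genes with a symbol, 5803 (34.1%) differed at an adjusted p under 0.05 in limma, 3176 higher and 2627 lower. At least 2-fold changes numbered 737 higher and 343 lower. Among 13756 probes without a symbol, 1641 were higher and 1947 lower. The background level of the EGr arrays lay 0.43 below that of the controls. That lowers dim genes that escaped the filter, so an unknown part of the falls may not be changes in expression. The controls differed among themselves in the level of the E1A spike-in probes, and without control replicates 1 and 2 the calls numbered 4096, of which 3653 were shared with the full comparison in the same direction.

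**Figure D1:**
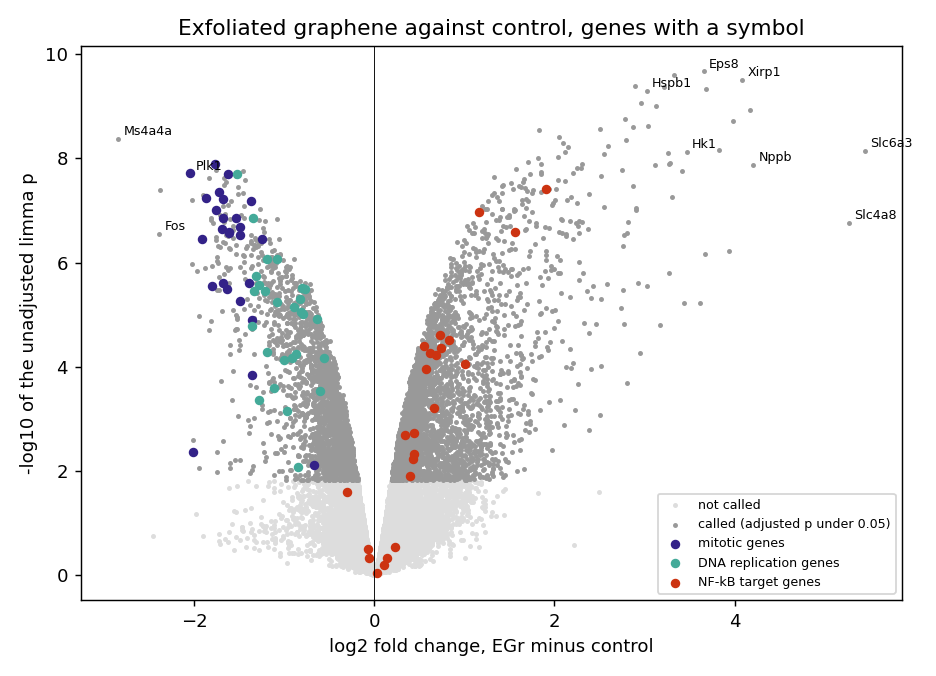
Each point is a gene with a symbol, with the log2 fold change (EGr minus control) on the x axis and -log10 of the unadjusted limma p on the y axis. Dark grey points are the 5803 called genes, and coloured points are the members of 3 gene lists, with all 26 mitotic and all 27 DNA replication genes on the left.

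The largest rises included genes best known from other tissues. Slc6a3, the dopamine transporter, rose by 5.44 ± 0.20 (43.5-fold, adjusted p = 7.7e-06), from a control mean of -0.01 ± 0.43 (SD) to 5.44 ± 0.10 (SD). Slc4a8, a sodium bicarbonate transporter, rose by 5.27 ± 0.30 (38.5-fold). Nppb, which encodes natriuretic peptide B, lay at the background level on all 4 control arrays and was at least 18.5-fold higher. Next came the germ cell gene Gsg1 (4.17 ± 0.12), Xirp1, an actin-binding gene of striated muscle (4.08 ± 0.10), Tmbim1 (3.99 ± 0.13), the prolactin family gene Prl7a3 (3.94 ± 0.26) and the epidermal gene Sbsn (3.83 ± 0.14). The dynein regulatory complex gene Drc3 (3.68 ± 0.10), the keratin gene Krt76 (3.67 ± 0.25), Eps8, whose protein caps actin filaments (3.66 ± 0.09), and the transcription factor gene Nfatc2 (3.62 ± 0.33) completed the 12. Of the 737 genes at least 2-fold higher, 42 lay at the background on all control arrays. Olfactory receptor genes, chosen after the values were seen as genes with little reason to be active in macrophages, were at least 2-fold higher in 32 of 745 cases (4.30%), against 4.33% of all genes, and at least 2-fold lower in 4 (0.54%), against 2.01%.

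The largest falls included a myeloid membrane gene, an immediate early gene and genes of mitosis. Ms4a4a, a surface protein of macrophages, fell by 2.85 ± 0.10 (7.19-fold lower, adjusted p = 6.8e-06) and Fos, a subunit of the AP-1 transcription factor, by 2.39 ± 0.15 (5.23-fold). The mitotic genes Plk1, Troap (-2.03 ± 0.10), Nek2 (-2.01 ± 0.50), Kif2c (-1.96 ± 0.15) and Ccnb2 were among the 12. The others were Fsd1 (-2.38 ± 0.11), Nat8f3 (-2.01 ± 0.46), Lypd8l1 (-1.90 ± 0.09) and 2 genes of skeletal muscle, Tnnt1 (-2.02 ± 0.15) and Myod1 (-1.95 ± 0.19). After subtraction of the background profile, Troap lay within the filter's limit of its own lowest value on 3 of the 4 EGr arrays. Its fall may therefore be a bound. For Ms4a4a, Fsd1, Ccnb2 and Lypd8l1 that count was 2. The count always includes the lowest array itself, so a count of 2 does not show that these genes followed the profile. Whether their falls are bounds is not known. The call of Nek2 ended without control replicate 1 (adjusted p = 0.0508) or 2 (adjusted p = 0.0547) and with the spike-in level as a covariate (adjusted p = 0.0668), and those of Nek2 (0.139) and Nat8f3 (0.0891) ended without both.

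**Figure D2:**
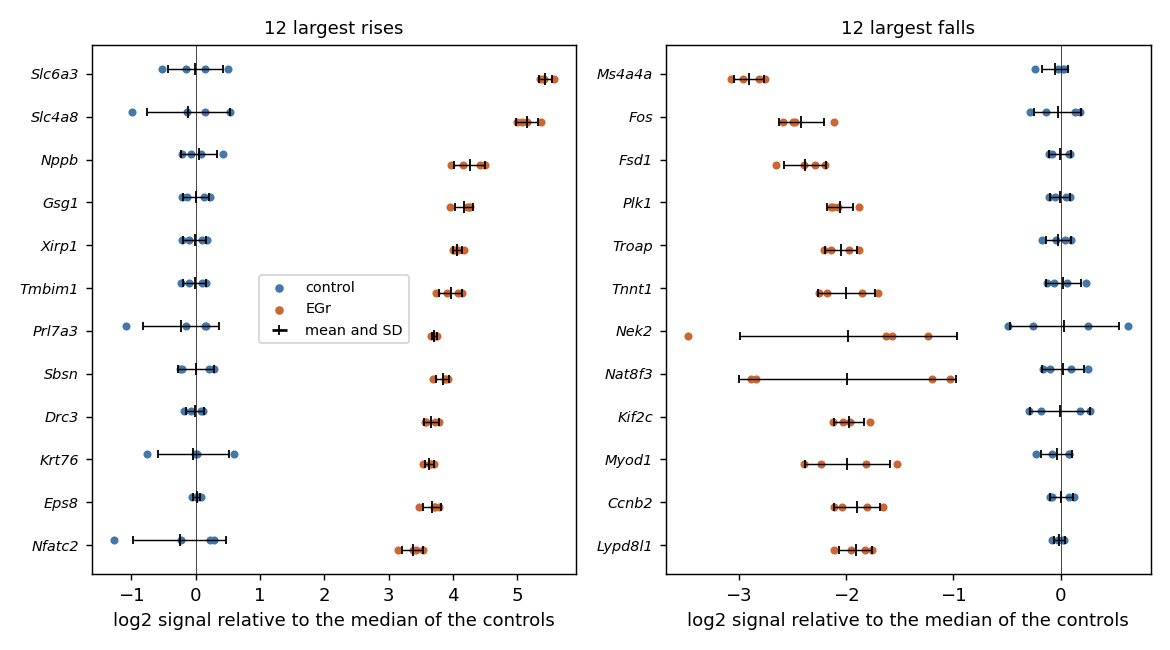
Points give each array's log2 signal relative to the median of the controls for the 12 largest rises (left) and falls (right), with the mean and SD of the 4 arrays of a group as bars. The groups do not overlap for any of these genes, and the EGr values of Nek2 and Nat8f3 are the most spread.

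All 26 measured mitotic genes fell, with a median of -1.63. They were also called when adjusted over the list alone, which must follow when every member is called over all features. Examples beside Plk1 and Ccnb2 are the proliferation marker Mki67 (-1.68 ± 0.09), Top2a, which untangles chromosomes (-1.69 ± 0.10), and the spindle checkpoint kinase Bub1 (-1.49 ± 0.09). All 27 measured DNA replication genes fell as well, with a median of -1.004, and the same holds for their adjustment over the list alone. Ribonucleotide reductase Rrm2 fell by 1.53 ± 0.07, thymidine kinase Tk1 by 1.36 ± 0.14 and the S-phase regulator E2f1 by 1.34 ± 0.07. Among p53 target genes 7 rose and 2 fell of 18 (7 and 3 adjusted over the list alone), with Rrm2b, a ribonucleotide reductase subunit used in DNA repair, at 1.58 ± 0.20, Ccng1 at 1.41 ± 0.07 and Gadd45a, which acts in growth arrest, at 1.25 ± 0.07. The cell cycle inhibitor gene Cdkn1a rose by 0.59 ± 0.06, and Bax, which promotes cell death, fell by 0.50 ± 0.07. Against all other genes, camera with a preset correlation gave adjusted p = 2.2e-23 for the mitotic list, 4.2e-19 for DNA replication and 0.158 for p53 targets (0.0371 with each probe as its own feature, and 0.378 for averaged genes with an estimated correlation). With an estimated correlation the adjusted p was 0.084 for both the mitotic and the DNA replication list, which ended both calls.

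Of 24 NF-kB target genes 17 rose and 0 fell (17 and 1 adjusted over the list alone), with a median of 0.50. The inhibitor of apoptosis Birc3 rose by 1.56 ± 0.09, the adhesion molecule Icam1 by 1.16 ± 0.06, the NF-kB subunit gene Relb by 1.01 ± 0.14 and Nfkbia, which encodes an inhibitor of NF-kB, by 0.68 ± 0.09. The camera adjusted p was 1.2e-06 with the preset correlation and 0.084 with an estimated correlation. Of 21 inflammatory cytokine genes 9 rose and 3 fell (10 and 4 adjusted over the list alone), with a median of 0.46. Inhba (8.73-fold), the macrophage growth factor gene Csf1 (2.33 ± 0.24), the interleukin 1 receptor antagonist gene Il1rn (2.04 ± 0.08) and Tnf (1.40 ± 0.11) were higher. Il1b (-0.52 ± 0.07) and Il18 (-0.48 ± 0.07), whose products are released after cleavage by inflammasomes, were lower. The camera adjusted p of the cytokine list was 0.0219 with the preset correlation, 0.288 with an estimated correlation and 0.0634 with the stricter filter.

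Chemokine genes went both ways, with 5 higher and 5 lower of 20 (6 and 5 adjusted over the list alone). Ccl4 rose by 2.18 ± 0.11 and Ccl22 by 1.31 ± 0.10, while the monocyte attractants Ccl2 and Ccl12 fell by 0.59 ± 0.11 and 0.69 ± 0.10. In the inflammasome and pyroptosis list 2 rose and 5 fell of 15, in the same numbers adjusted over the list alone. The sensor Nlrp3 fell by 0.94 ± 0.12 and the adaptor Pycard by 0.78 ± 0.07, while Txnip rose by 0.40 ± 0.09. Of 24 type I interferon response genes 6 rose and 4 fell (7 and 5 adjusted over the list alone), among them Oasl (2.00 ± 0.15) and Rsad2 (1.56 ± 0.10) higher and Oasl2 (-0.69 ± 0.12) and Ifi44 (-0.61 ± 0.09) lower. None of these 3 lists passed camera, with adjusted p = 0.607 for chemokines, 0.391 for the inflammasome and 0.607 for the interferon response.

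**Figure D3:**
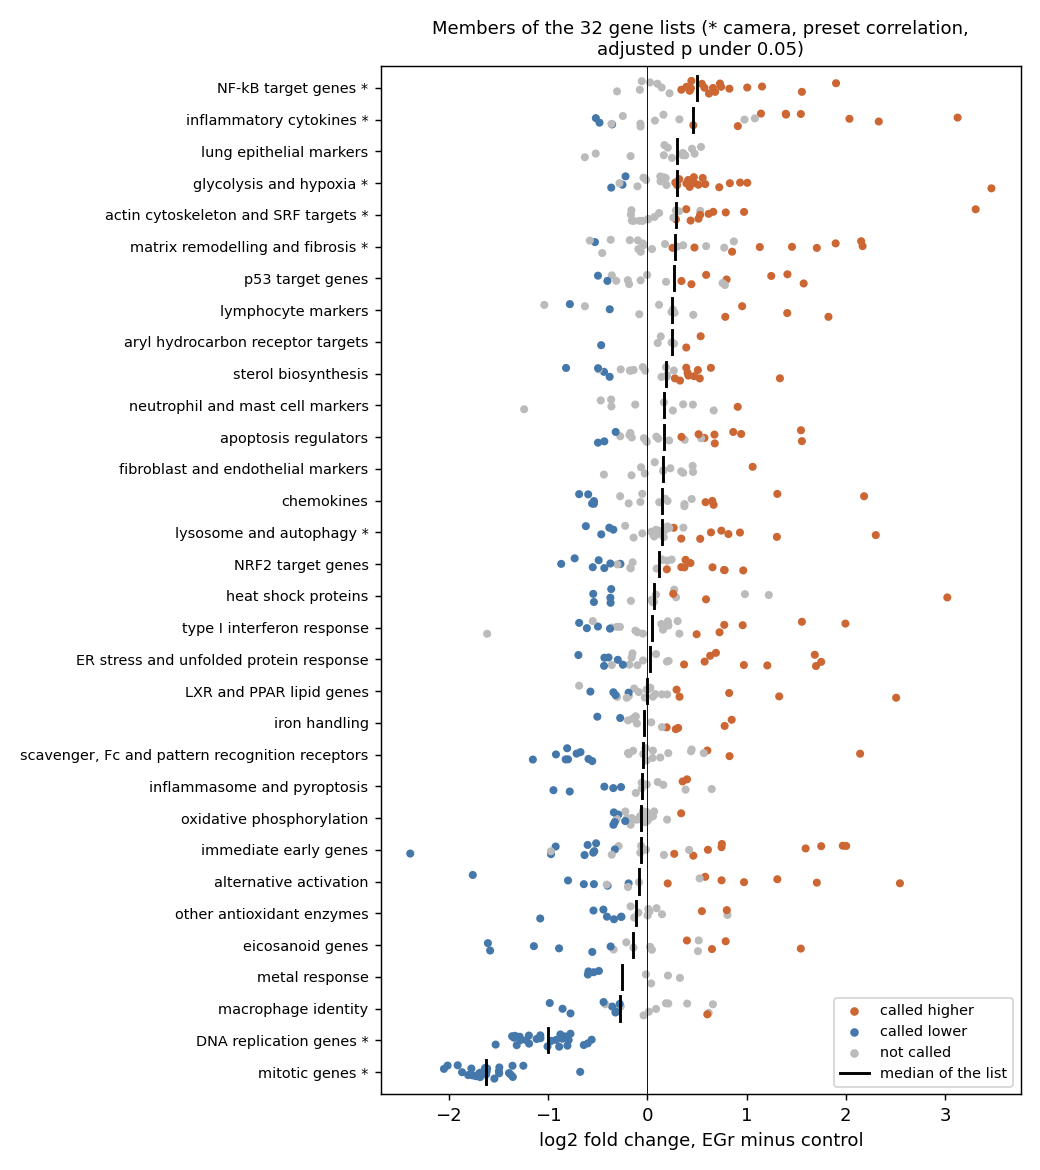
Each row is a gene list, 32 in all, each point a measured member with its log2 fold change (EGr minus control) on the x axis, and each black bar the median of the list. The mitotic (median -1.63) and DNA replication (median -1.004) lists lie wholly to the left of 0, and most other lists hold called members on both sides.

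Stress genes were called in both directions. In the list of ER stress and the unfolded protein response 9 rose and 6 fell of 24 (10 and 6 adjusted over the list alone). The transcription factor genes Atf3 (1.75 ± 0.09) and Ddit3 (1.69 ± 0.08) and their partner Trib3 (1.70 ± 0.08), all known to be induced through ATF4, were higher, while the ER-resident protein disulfide isomerases Pdia4 (-0.69 ± 0.07), Pdia3 (-0.43 ± 0.06) and Pdia6 (-0.43 ± 0.06) were lower. The small heat shock protein gene Hspb1 rose 8.13-fold (3.02 ± 0.08), but its list counted 3 higher and 5 lower of 17 (4 and 5 adjusted over the list alone), with the HSP90 co-chaperone genes Fkbp4 and Ahsa1 both at -0.54 ± 0.08. Immediate early genes were 9 higher and 9 lower of 26 (10 and 9 adjusted over the list alone). The AP-1 member Fosl1 (2.00 ± 0.19) and Maff (1.97 ± 0.19) rose, against falls of Fos and of the phosphatase genes Dusp1 (-0.97 ± 0.16) and Dusp6 (-0.92 ± 0.08). Of 24 apoptosis regulators 9 rose and 3 fell (11 and 3 adjusted over the list alone), with Birc2 (1.55 ± 0.08) and Fadd (0.95 ± 0.08) higher and Bmf (-0.43 ± 0.07) lower. Adjusted p in camera was 0.391 for ER stress, 0.857 for heat shock, 0.857 for immediate early genes and 0.0686 for apoptosis. The apoptosis list passed without the filter on dim probes (0.0245) and with each probe as its own feature (0.0371), both with the preset correlation, while an estimated correlation gave 0.262 for the list of averaged genes.

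The list of NRF2 targets, the main response to oxidants, had 9 higher and 7 lower of 26 (9 and 9 adjusted over the list alone). Heme oxygenase Hmox1 rose by 0.78 ± 0.07 and malic enzyme Me1 by 0.77 ± 0.09, while glutathione transferase Gstp1 fell by 0.87 ± 0.07 and glutathione reductase Gsr by 0.55 ± 0.08. Other antioxidant enzymes were 2 higher and 7 lower of 18, the same adjusted over the list alone, with Msra at 0.80 ± 0.08, Sod2 at 0.55 ± 0.07 and glutaredoxin Glrx at -1.08 ± 0.07. Of 8 metal response genes 0 rose and 4 fell (1 and 4 adjusted over the list alone), among them the metallothionein genes Mt1 (-0.60 ± 0.08) and Mt2A (-0.59 ± 0.09). Iron handling had 5 higher and 2 lower of 14, the same adjusted over the list alone, with the phagosomal metal transporter gene Slc11a1 at 0.85 ± 0.07 and ceruloplasmin Cp at -0.50 ± 0.08. Aryl hydrocarbon receptor targets had 2 higher and 1 lower of 7, the same adjusted over the list alone, with Tiparp at 0.54 ± 0.08. Adjusted p in camera was 0.857 for NRF2, 0.315 for other antioxidants, 0.278 for metal response, 0.597 for iron and 0.315 for the aryl hydrocarbon receptor.

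Of 29 genes of glycolysis and hypoxia 16 rose and 3 fell, the same adjusted over the list alone, with a median of 0.30. Hexokinase Hk1 rose 11.1-fold (3.47 ± 0.13), Adm by 0.94 ± 0.11 and the lactate transporter gene Slc16a3 by 0.83 ± 0.10, and pyruvate kinase Pkm fell by 0.36 ± 0.08, a call that ended without control replicates 1 and 2 (adjusted p = 0.0864). Camera gave adjusted p = 0.0044 with the preset and 0.193 with an estimated correlation. In oxidative phosphorylation 1 rose and 5 fell of 26 (1 and 3 adjusted over the list alone), with Ndufb8 at -0.34 ± 0.07, and the camera adjusted p was 0.17. Sterol biosynthesis had 10 higher and 4 lower of 26 (12 and 6 adjusted over the list alone, camera adjusted p = 0.278, and 0.015 with a median of 0.29 against 0.19 when each probe was its own feature, against 0.386 for averaged genes with an estimated correlation), with Hsd17b7 at 0.64 ± 0.07, Insig1 at 0.53 ± 0.09 and Tm7sf2 at -0.82 ± 0.08. Of 23 LXR and PPAR lipid genes 5 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.687). The fatty acid carrier Fabp4 rose by 2.51 ± 0.08, the lipid droplet protein gene Plin2 by 1.33 ± 0.06 and the cholesterol exporter gene Abca1 by 0.83 ± 0.08, and Acadm, of fatty acid oxidation, fell by 0.57 ± 0.07.

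Of 29 genes of the lysosome and autophagy 9 rose and 4 fell (12 and 4 adjusted over the list alone), with a median of 0.15. The protease cathepsin K (Ctsk) rose by 2.30 ± 0.09, the autophagy receptor gene Sqstm1 by 1.31 ± 0.07 and the proton pump gene Atp6v0d2 by 0.93 ± 0.07, while Hexa (-0.62 ± 0.08) and cathepsin S (Ctss, -0.38 ± 0.07) fell. Camera gave adjusted p = 0.0219 with the preset and 0.491 with an estimated correlation. The call also ended without control replicate 3 (0.0693), control replicate 4 (0.0839) or EGr replicate 1 (0.0603), and with the stricter filter (0.0634). Matrix remodelling and fibrosis had 9 higher and 1 lower of 26 (11 and 4 adjusted over the list alone), with a median of 0.28. The gelatinase gene Mmp2 (2.15 ± 0.08) and the protease inhibitor gene Serpinb2 (1.90 ± 0.11) rose, and Mmp7 fell by 0.53 ± 0.11. Camera gave adjusted p = 0.0135 with the preset and 0.379 with an estimated correlation. Of 24 actin cytoskeleton and SRF target genes 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.29. Ezr, which links actin to the membrane, lay at the background on all control arrays and was at least 9.91-fold higher, and vinculin Vcl rose by 0.79 ± 0.15. The list's camera adjusted p was 0.0219 with the preset and 0.379 with an estimated correlation, 0.0839 without control replicate 4, and 0.148 with the stricter filter.

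Receptors and identity genes of macrophages counted more called falls than called rises. Of 25 scavenger, Fc and pattern recognition receptors 3 rose and 9 fell, the same adjusted over the list alone, with the scavenger receptor gene Olr1 at 2.14 ± 0.11, the immunoglobulin receptor gene Fcgr1a at -1.15 ± 0.09, Axl at -0.92 ± 0.19 and Tlr4 at -0.82 ± 0.09. Macrophage identity genes had 1 higher and 8 lower of 20, the same adjusted over the list alone, with Cd14 at 0.61 ± 0.09 and Aif1 at -0.85 ± 0.08. Genes of alternative activation had 7 higher and 6 lower of 17, the same adjusted over the list alone. Arginase Arg1 rose by 2.55 ± 0.13 and transglutaminase Tgm2 by 1.71 ± 0.09, while the lectin gene Clec10a fell by 1.76 ± 0.11 and the mannose receptor gene Mrc1 by 0.80 ± 0.09. Eicosanoid genes had 4 higher and 6 lower of 17, the same adjusted over the list alone. The genes of leukotriene synthesis Alox5 (-1.60 ± 0.11) and Alox5ap (-1.58 ± 0.27) and the cyclooxygenase gene Ptgs1 (-1.14 ± 0.08) fell, and the prostaglandin receptor gene Ptger2 rose by 0.79 ± 0.08. The camera adjusted p was 0.278 for the receptors, 0.158 for macrophage identity, 0.597 for alternative activation and 0.295 for eicosanoids.

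Markers of other cell types were measured in 4 lists. Lymphocyte markers had 4 higher and 2 lower of 14, with Cd2 at the background on all control arrays and at least 3.54-fold higher, Cd3d at 0.96 ± 0.11 and Nkg7 at -0.78 ± 0.13. Neutrophil and mast cell markers had 1 higher and 0 lower of 11 (Kit, 0.91 ± 0.18), a call that ended without control replicates 1 and 2 (adjusted p = 0.0557). Fibroblast and endothelial markers had 1 higher and 0 lower of 13 (Dcn, 1.06 ± 0.08). None of 14 lung epithelial markers passed, with Sftpd at 0.48 ± 0.18 (adjusted p = 0.0809) and Scgb1a1 at 0.36 ± 0.14 (adjusted p = 0.0842) nearest to it. These counts were the same adjusted over the list alone, and the camera adjusted p was 0.41, 0.679, 0.278 and 0.328 in that order.

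Of the 32 lists, 8 passed camera with the preset correlation and 0 with an estimated correlation. The rotation test fry, which asks whether a list moves one way without comparing it with other genes, passed 28, and its mixed form, which asks for change in either direction, passed 32. Median, mean and camera direction differed in sign for iron handling, LXR and PPAR lipid genes, alternative activation and immediate early genes. The arrays themselves differed in the level of the E1A spike-in probes, at -0.94 on average for control replicates 1 and 2 and 1.08 for control replicates 3 and 4, against 0.91 ± 0.40 (SD) for EGr. The background level was 0.06 ± 0.27 (SD) in controls and -0.37 ± 0.14 (SD) in EGr, a difference of -0.43 (exact permutation test, two-sided, p = 0.0571, where the smallest possible is 0.0286).

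**Figure D4:**
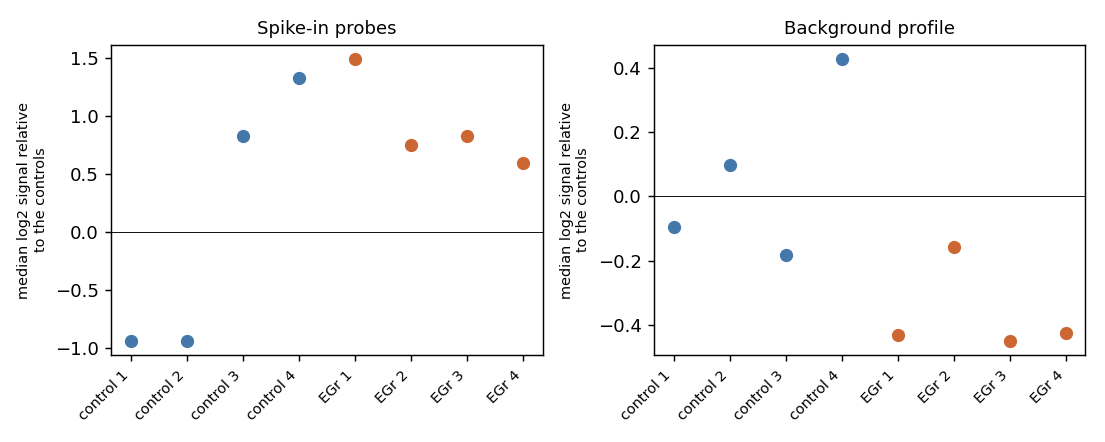
Each point is an array, controls in blue and EGr in orange, with the median log2 signal of the E1A spike-in probes (left) and of the control probes that carry the background level (right), both relative to the controls. Control replicates 1 and 2 lie near -0.94 for the spike-ins, and the other 6 arrays lie between 0.60 and 1.49.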

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

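In this part, the median shift as a test of scaling and the gap between the mitotic and replication lists were chosen after the results were seen. The criterion that would exclude an equal fall of all cycling genes was also rewritten after its result was known, as stated below. The patterns were picked after the first results, and the criteria of the other tests were written before those tests were run.

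The count of called genes was set against other splits of the 8 arrays into 4 and 4. Of 35 splits, 1 gave as many genes as the real one, namely itself with 5803, and the highest of the others gave 0. A share of 1 of 35 is the smallest that this test can reach. Every other split mixes control and EGr arrays, so a difference between the groups adds to the spread within each side and lowers the count. The real split thus ranked highest, but chance is not excluded by these counts. The ranking also does not tell exposure from anything else shared by the arrays of a group.

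The fall of the mitotic and DNA replication genes held all 53 measured members. A shift of whole arrays would move all genes alike and is argued against by the median of all genes, 0.04 in the values as deposited. A median shift of each array moved little, and the median of the 53 genes was then -1.35. The spike-in difference among the controls is argued against by a median of -1.24 when only control replicates 3 and 4, whose spike-in level is that of the EGr arrays, served as controls. What stays open is whether fewer cells were cycling or each cycling cell held less of these transcripts. The mitotic median lay 0.62 below the replication median (mitotic minus replication -0.62, permutation test exchanging genes between the lists, p = 1e-05, the smallest that 100000 resamples can give, with genes not independent replicates). That gap may come from different levels of these genes in cells that do not cycle, which were not measured, so it decides nothing. The criterion first written counted a gap over 0.2 with a small permutation p as excluding an equal fall, and by it an equal fall would be excluded. It was set aside because such levels can open a gap. The criterion put in its place, a share of these genes called higher, tests nothing, since all of them were already known to be lower. Whether the exposure or anything else shared by the arrays of a group underlies the fall was not tested.

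The E1A spike-in probes split the controls, with replicates 3 and 4 higher than 1 and 2 by 2.02 (4.05-fold). Between these pairs limma called 0 genes after adjustment (0% of 17029), which would meet the bound set beforehand for a difference in spike-in amount alone. That test is void, as judged after its result, because the other splits of the 4 controls into pairs also gave 0, so an unequal amount of spike-in RNA stays open. At an unadjusted p under 0.05 the split by spike-in level gave 2585 genes against 727 and 443 in the other splits, which goes with a labelling or hybridisation difference that moved gene signals too. No biological explanation was tested, since the labels do not distinguish these controls.

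Genes at the background on all control arrays were called higher in 70 cases, with a median rise of 1.12. In the other direction, genes at the background on all EGr arrays were called lower in 58 cases. The background of the EGr arrays lay 0.43 lower, which lowers genes at that level. Of the 4214 probes removed as background 373 would have been called, all lower. That follows from their selection by the background profile and is no separate support. Since a deeper background lowers such genes, it is argued against as the cause of the rise by its direction. The bound set beforehand, a rise over 2 times that gap, was met as well but allowed for a rise that a deeper background cannot give. The genes were picked for being called higher, so the size of the rise is selected and carries no weight here. An unspecific gain of dim probes stays open. Olfactory receptor genes were called higher in 11.01% of 745 cases against 18.7% of all genes, which lies between the bounds set beforehand for and against it. At least 2-fold rises were as frequent among them (4.30%) as among all genes (4.33%), which goes with such a gain. Their median log2 change was -0.18, where that of all genes was 0.04, and 16.4% of them were called lower against 15.4% of all genes. Whether these receptor genes are dim was not measured. The deeper background would lower them if they are, so these falls decide neither for nor against such a gain. These shares and medians were looked at only afterwards. Induction of silent genes by the exposure also stays open and was not tested.

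Single arrays stood apart from the other 3 of their group in 4 of 122 groups of values checked, where chance gives about 1 in 20. The background level of EGr replicate 2 was -0.16, against -0.45 to -0.43 in the other EGr arrays. In the same array 0.359% of probes lay more than 2 from the median of the group, against 0.0326% to 0.0598%. The median of the alternative activation list was -0.077 in EGr replicate 3, against 0.15 to 0.20. The log2 value of Gsg1 was 3.96 in EGr replicate 1, against 4.22 to 4.26. Among the 91 control probes, which enter no comparison, 2 had every EGr array above every control array, and 11 had every EGr array below.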

How the results depend on the processing

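Robust empirical Bayes, single probes as features, the fit without control replicates 1 and 2 and the spike-in covariate were chosen after seeing the data. Calls of 5803 genes ranged from 4148 (without EGr replicate 3) to 5392 with 1 array left out, higher genes from 2356 to 3035 and lower genes from 1792 to 2404. The median shift gave 5586 calls (5441 shared in direction), no filter 5552 (5426), the stricter filter 5092 (4645), array weights 6951 (5664), robust empirical Bayes 5645 (5645) and the spike-in covariate 5229 (4738). Without control replicates 1 and 2 the lower genes numbered 1729, with fewer samples. Stricter thresholds gave 2663 genes at 1.5-fold or more (1652 higher, 1011 lower), 1080 at 2-fold or more (737 and 343) and 3093 at an adjusted p under 0.01 (1791 and 1302).

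The replicate block gave 4782 calls, 4509 of them (77.7%) shared. Whether the numbers pair the samples is not known. The correlation of same-numbered arrays was at most 0.073, 0 of 4 pairs passed 0.1 and 2 of 4 controls correlated best with their own number. Such low correlations show no strong pairing but cannot exclude that same-numbered samples were handled together.

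Calls gained were those of the apoptosis list without the filter (adjusted p = 0.0245, 9 lists in all) and of the sterol (0.015), p53 (0.0371) and apoptosis (0.0371) lists with each probe as its own feature (11 lists). Probes of the same gene are not independent members, so the p-values of that last setting may be too small. Lists passing camera numbered 6 (without control replicate 4) to 8 with 1 array left out, 8 with the replicate block, 5 with the stricter filter, 0 with an estimated correlation, and 28 and 32 with fry and mixed fry, which test something else. Under the stricter filter the medians of lists no longer called were 0.69 for cytokines, 0.15 for the lysosome and 0.28 for actin genes. With the estimated correlation medians stayed by construction at 0.46 for cytokines, 0.50 for NF-kB, 0.15 for the lysosome, 0.28 for matrix, -1.63 for mitotic, -1.004 for replication, 0.30 for glycolysis and 0.29 for actin genes. With 1 array left out, medians ranged from 0.42 to 0.62 for cytokines, 0.49 to 0.52 for NF-kB, 0.11 to 0.18 for the lysosome, 0.25 to 0.33 for matrix, -1.67 to -1.58 for mitotic, -1.07 to -0.97 for replication, 0.25 to 0.34 for glycolysis and 0.25 to 0.33 for actin genes. Of 161 called named genes, 143 (without EGr replicate 3) to 157 kept their call with 1 array left out, and 133 without control replicates 1 and 2. Over 16 settings 129 kept it in every setting that measured them, and none changed direction. The stricter filter left 28 of the 161 unmeasured. Where a call was lost, the cause was not tested. Quantile normalisation, normexp, the variance trend and the slide block were not run, since the values hold no signals or slides. Signal over background limits genes near the background profile, where folds are bounds.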

Other observations

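The gene families here were defined by their symbols after the data were seen, and all tests in this part were chosen then.

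Centromere proteins, which carry the attachment of chromosomes to the spindle, were lower in 17 of 19 measured members and higher in 0, with a median log2 change of -1.24. Cenpt (-1.71 ± 0.09), Cenpf (-1.68 ± 0.08), Cenpw (-1.67 ± 0.10) and the centromeric histone gene Cenpa (-1.65 ± 0.09) led them. Camera adjusted p over the 12 families was 1.1e-14 with the preset correlation and 0.049 with an estimated correlation. Kinesins, motors that walk on microtubules, were lower in 10 and higher in 3 of 33 (adjusted p = 0.0455 with the preset, 0.434 with an estimated correlation). The falls were led by the mitotic motors Kif2c, Kif14 (-1.88 ± 0.14) and Kif23 (-1.87 ± 0.09), while the axonal motor Kif5a rose by 0.97 ± 0.15 and Kif3a, of transport in cilia, by 0.66 ± 0.06. Histone genes were lower in 14 and higher in 5 of 32, with the linker histone H1f5 at -1.51 ± 0.18 and H2ax, which marks DNA breaks, at -1.13 ± 0.08 (adjusted p = 0.0455 with the preset, 0.494 with an estimated correlation).

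Cytosolic ribosomal protein genes were lower in 29 of 69 and higher in 0, by a small amount, with a median of -0.22 and Rpl15 at -0.55 ± 0.08 (adjusted p = 1.7e-09 with the preset, 0.434 with an estimated correlation). Mitochondrial ribosomal protein genes had 8 higher and 12 lower of 67. Proteasome genes had 8 higher and 4 lower of 38, and 2 of those lower, Psmb9 (-0.63 ± 0.09) and Psmb10 (-0.37 ± 0.08), encode subunits of the immunoproteasome. Collagens were higher in 10 and lower in 3 of 36, with Col6a1 at the background in all controls and at least 10.7-fold higher (adjusted p = 0.0393 with the preset, 0.434 with an estimated correlation). Genes of axonemal dyneins and radial spokes, which move cilia, were higher in 7 and lower in 0 of 24, among them Rsph4a (3.17 ± 0.33) and Dnai2 (1.20 ± 0.07), with adjusted p = 0.0267 with the preset and 0.434 with an estimated correlation. Keratins had 7 higher and 2 lower of 33, solute carriers 78 higher and 50 lower of 318, and integrins 6 higher and 6 lower of 28. Olfactory receptors had 82 higher and 122 lower of 745, with Or2h15 at 2.82 ± 0.16. Camera with the preset correlation gave adjusted p = 0.157 each for keratins, solute carriers and olfactory receptors. It gave 0.373 for the proteasome and 0.636 each for integrins and mitochondrial ribosomal proteins.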
